A study of Mus musculus with 14 samples.

How the data were processed

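Heads of mouse embryos at E8.5 (5 to 7 somites) of mixed strain background gave total RNA, which was isolated on QIAGEN micro columns, labelled with biotin and hybridised to Illumina bead arrays, per the labels' protocols. The 14 arrays hold 4 genotypes, taken from the genotype label of each sample. Control heads carry 1 floxed and 1 wild-type Twist1 allele and no Cre (n = 4). CM-Het heads carry the same Twist1 alleles and Cre knocked in at Mesp1 (n = 3). Het heads carry 1 floxed and 1 deleted Twist1 allele and no Cre (n = 3), and CM-CKO heads carry those Twist1 alleles together with Mesp1-Cre (n = 4). The array descriptions place the CM-Het and Het arrays on beadchip 1, the Control arrays and CM-CKO 1 and 2 on beadchip 2, and CM-CKO 3 and 4 on beadchip 3. Nothing says whether replicates are separate embryos, litters or pools, so p-values measure only the spread between these samples. Xist or Y-linked signal differs between arrays within each genotype, so the arrays of a genotype do not all hold the same material.

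The deposited signal intensity is a linear bead summary per probe, neither normalized nor background subtracted, per the file headers and the range of its values. Its median ran from 92.3 (Control 4) to 116 (Het 1). The scanner and the summary software are not given in the sources used here. A deposited detection p-value stands beside each intensity, per the file headers. A further deposited table holds processed log2 values with a median of 6.72 on every array, which equal the log2 intensities after quantile normalization to within 0.0379, without background subtraction. That table served as an alternative.

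The deposited detection p-values do not sit on the rows of their intensities. On every array the rank correlation of intensity and detection p lay between -0.105 and -0.0946, although a detection p should fall steadily as the intensity rises. The p-values were therefore put back by rank within each array. For 45259 of 45281 probes the 14 restored p-values occur together as 1 deposited row, whereas 12.3% of the p-values, and all 14 of them for 4340 probes, were already in place. Over 5053 pairs of probes of the same gene, the share of arrays with detection correlated at 0.243 (rank correlation) in the deposited order and 0.412 after restoring, against 0.432 for the intensity itself. The restored order follows the intensity by construction, so the nearness of 0.412 to 0.432 is no separate support for it. With the deposited order the background step compressed all values to between 4.70 and 4.72 on the log2 scale and could not be used. This step was chosen after the values were seen. The filter on dim probes was also run with the deposited order as an alternative.

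Intensities were background corrected and quantile normalized with neqc of limma 3.58.1 in R 4.3.3 (offset 16, negative controls inferred from the detection p). A probe counted as detected at a detection p under 0.05 on at least 3 arrays. Between 18242 (Control 2) and 19455 (Control 3) of 45281 probes were at a detection p under 0.05 on a single array, 40.3% to 43.0%. Of all probes, 34885 have 1 gene symbol, 18 have several and 10378 have none in the platform annotation. The symbols of 34807 probes matched the RefSeq gene table of assembly GRCm38.p6, and 0 symbols were changed through Entrez numbers. The files name no genome build, so that table was used only for names and for which genes neighbour each other. Of 17991 detected named probes, the brightest of each gene over all arrays was kept, which gave 11394 genes. For 4458 of them another detected probe exists. The 3109 detected probes with no or several symbols were tested apart.

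Group means over all 14 arrays were fitted with limma (lmFit, eBayes with a trend), and every adjusted p of a gene is from limma with Benjamini-Hochberg adjustment over the 11394 genes, called under 0.05. Besides all pairs of genotypes, 3 contrasts were formed: Cre averaged over the second Twist1 allele, the deleted allele averaged over Cre, and their interaction. In both averages a shift between beadchips 1 and 2 cancels, while it adds to the interaction. A shift of beadchip 3, which holds only CM-CKO arrays, does not cancel in either average. Twist1 and Mesp1 were also compared by two-sided exact permutation tests. A probe not above background on any array of a group has only a bound there. Its fold is then given as at least the brighter mean over the higher of the dim signal and the lowest detected signal of each array.

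Before the data were examined, 27 gene lists were fixed (502 members, 383 of them tested), for Twist1 and its partners, head mesenchyme transcription factors, branchiomeric progenitors, extracellular matrix, cell-matrix receptors, mesenchymal and epithelial state, neural tube, neural crest, endothelium, primitive erythroid cells, myeloid cells, heart muscle, gut endoderm, yolk sac endoderm, surface ectoderm, the FGF, BMP and TGF-beta, WNT, hedgehog, NOTCH and retinoic acid pathways, p53 targets, cell division, hypoxia and glycolysis, immediate early and heat shock genes, and sex-linked genes. Some genes stand in more than 1 list. Each list was compared with all other tested genes by camera (preset correlation 0.01, adjusted over lists), again with the estimated correlation, and by fry. Also fixed were the design, the alternatives below, other than the last 3, and the rule for named genes. That rule takes up to 15 genes with the largest positive and 15 with the largest negative called differences in CM-CKO against Control, 6 and 6 in the other comparisons (all where fewer than 20 were called), up to 4 members of smallest p per list in CM-CKO against Control, and Twist1 and Mesp1 always. Genes outside it are named near the engineered loci and as histone genes, and were chosen after their values were seen. Gene neighbourhoods of 10 Mb around Twist1 and Mesp1 were compared with all other genes by Fisher's exact test.

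Alternatives covered background, scaling, the filter, the probes of a gene, array weights, the variance trend, the arrays in the fit, beadchip and replicate blocks, each array left out, the threshold, the window and the correlation of camera. Chosen after seeing the data were a heart marker covariate, the omission of the 3 arrays without Xist signal, and the deposited order of the detection p. The fit was tested on simulated data made from these arrays, with 200 of the 11394 genes changed. For CM-CKO against Control it recovered 54% of 50 genes changed by a log2 of 0.5 and 100% of those changed by 1, 1.5 or 2, and 5.35% of its calls were false. Camera called the shifted list in 50 of 50 draws, with 0.02 unchanged lists per draw. The simulated genes were drawn independently of each other, so this rate does not hold for lists of correlated genes. When the real CM-CKO and Control arrays were regrouped, the other groupings called a median of 3.5 lists. Within groups the arrays correlated at 0.987 to 0.994 and 0 pairs were identical. Precision is limited by the number of arrays. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.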

Results

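Gene expression was measured on 14 bead arrays of E8.5 mouse embryo heads to ask what Twist1, a bHLH transcription factor of head mesenchyme, does in the mesoderm that Mesp1-Cre marks. The genotypes were Control (n = 4), CM-Het with Cre and 1 floxed copy of Twist1 (n = 3), Het with 1 floxed and 1 deleted copy (n = 3) and CM-CKO with a floxed copy, a deleted copy and Cre (n = 4). Neural tissue, neural crest, ectoderm and endoderm share these heads with the mesoderm, so each value is a mixture of cell types.

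Twist1 signal was lower in each genotype with fewer intact copies. Its mean log2 signal was 9.32 ± 0.20 (SD, n = 4) in Control, 8.65 ± 0.14 (n = 3) in CM-Het, 8.60 ± 0.12 (n = 3) in Het and 7.75 ± 0.14 (n = 4) in CM-CKO. CM-CKO lay 2.95-fold below Control (log2 -1.56, SE 0.10, limma adjusted p = 1.28e-07), and the exact permutation p of 0.0286 was the smallest that 4 against 4 arrays allow. It also lay below Het (log2 -0.84, adjusted p = 0.00104) and CM-Het (log2 -0.90, adjusted p = 0.00089). CM-Het was below Control (log2 -0.66, adjusted p = 0.0296), a call lost without CM-Het 1, where the adjusted p rose to 0.15, and likewise without CM-Het 2, Het 2, Control 1, Control 3 or Control 4. Het differed from Control by log2 -0.72, which missed the limma threshold (adjusted p = 0.0823) while the exact permutation p was 0.0286. CM-Het and Het were 0.06 apart, within their spread. Within beadchip 2 the difference of CM-CKO from Control was -1.50 and with the 2 CM-CKO arrays of beadchip 3 it was -1.63, and the call was kept in both. Without the 3 arrays that lack Xist signal the calls of CM-CKO against Het (log2 -0.73, adjusted p = 0.124) and CM-Het (-0.83, 0.0572) and of CM-Het against Control (-0.66, 0.0608) were lost, at differences near those of all arrays and with fewer arrays. Whether the probe lies in the deleted part of Twist1 is unknown, so a remaining signal says nothing about the allele. Mesp1, which is switched off in mesoderm by this stage, had mean log2 signals of 4.23 to 4.32 and was above background on 0 arrays.

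**Figure D1:**
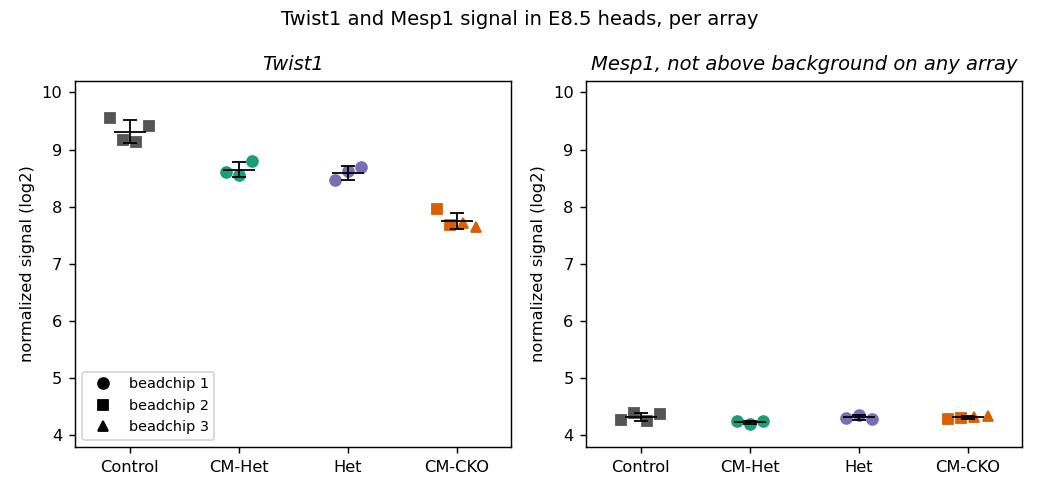
Normalized log2 signal of Twist1 (left) and Mesp1 (right) on each array, by genotype, with symbols for the beadchip and black bars for the mean and SD. All 4 CM-CKO arrays lie between 7.65 and 7.96 for Twist1 and all 4 Control arrays between 9.13 and 9.55, while Mesp1 stays at background.

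Loss of Twist1 in the Mesp1-Cre lineage, the main question of the design, was read from CM-CKO against Control. These genotypes also differ by a deleted Twist1 copy in the cells outside that lineage and by Cre knocked in at Mesp1. A call here therefore need not come from the loss in the lineage. Among the called genes other than Twist1 the largest decreases were as follows. Lum, the matrix proteoglycan lumican, fell 4.58-fold (log2 -2.19, SE 0.14, n = 4 and 4, adjusted p = 1.28e-07) and was above background on 2 of 4 CM-CKO arrays. Ebf3, a transcription factor of head mesenchyme, fell 3.17-fold (log2 -1.66, SE 0.11, adjusted p = 1.28e-07), and Cd248, a pericyte and fibroblast surface protein, 3.08-fold (log2 -1.62, SE 0.14, adjusted p = 2.53e-06). The transcription factors Alx4 (log2 -1.48), Tcf15 (log2 -1.32), Twist2 (log2 -1.31) and Snai2 (log2 -1.28) fell by 2.42-fold to 2.79-fold. The collagen processing factor Pcolce (log2 -1.48), the proteoglycan Bgn (log2 -1.47) and the scavenger receptor Scarf2 (log2 -1.50) fell by 2.76-fold to 2.83-fold. Vegfc, a growth factor for lymphatic vessels, changed by log2 -1.30, the carbonyl reductase Cbr3 by -1.27, the adhesion protein Tgfbi by -1.27 and the collagen chain Col6a1 by -1.18. In all, limma called 80 of 11394 genes, 21 higher and 59 lower.

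The higher genes changed less. Trh, thyrotropin-releasing hormone, rose 2.20-fold (log2 1.14, SE 0.16, adjusted p = 0.00116). The sensory neuron factor Pou4f1 rose by log2 0.94 (SE 0.14, adjusted p = 0.00247), the growth factor Gdnf by 0.89 (SE 0.14, adjusted p = 0.00402) and the monooxygenase Cyp1b1 by 0.82 (SE 0.15, adjusted p = 0.0108). Cdkn1a, a cell cycle inhibitor induced by p53, rose by 0.79, and Igfbp5, an IGF binding protein, by 0.54 from a high level of 12.2. Esm1 (0.96), Uncx (0.72), Lypd1 (1.09), Rbm47 (0.70), Tra2b (0.61), Ppm1h (0.58), Gper1 (at least 1.20-fold, below background in Control) and Pltp (at least 1.39-fold, likewise) were also called higher. The probe kept for Trappc12 read 1.35 higher (SE 0.24, adjusted p = 0.00737), but a second probe of this gene read -1.21 and another -0.03, so Trappc12 has no settled direction. Of the 80 called genes 30 had another detected probe, and 26 of these 39 other probes moved the same way at an unadjusted p under 0.05. Other probes read smaller differences for Ebf3 (-0.52, SE 0.14), Lum (-1.43, SE 0.13) and Cbr3 (-0.29, SE 0.16), and differences near 0 for Cdkn1a (0.05, beside 0.57 from a further probe), Ppm1h (0.05), Pax8 (0.04), Serpinf1 (-0.11) and Col26a1 (-0.10). For Uncx another probe read 0.17, and for Egfl7 2 others read 0.12, against its call, and -0.37. Folds therefore rest on the probe kept. Probes of Trappc12 were the only ones that moved the opposite way at that level.

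**Figure D2:**
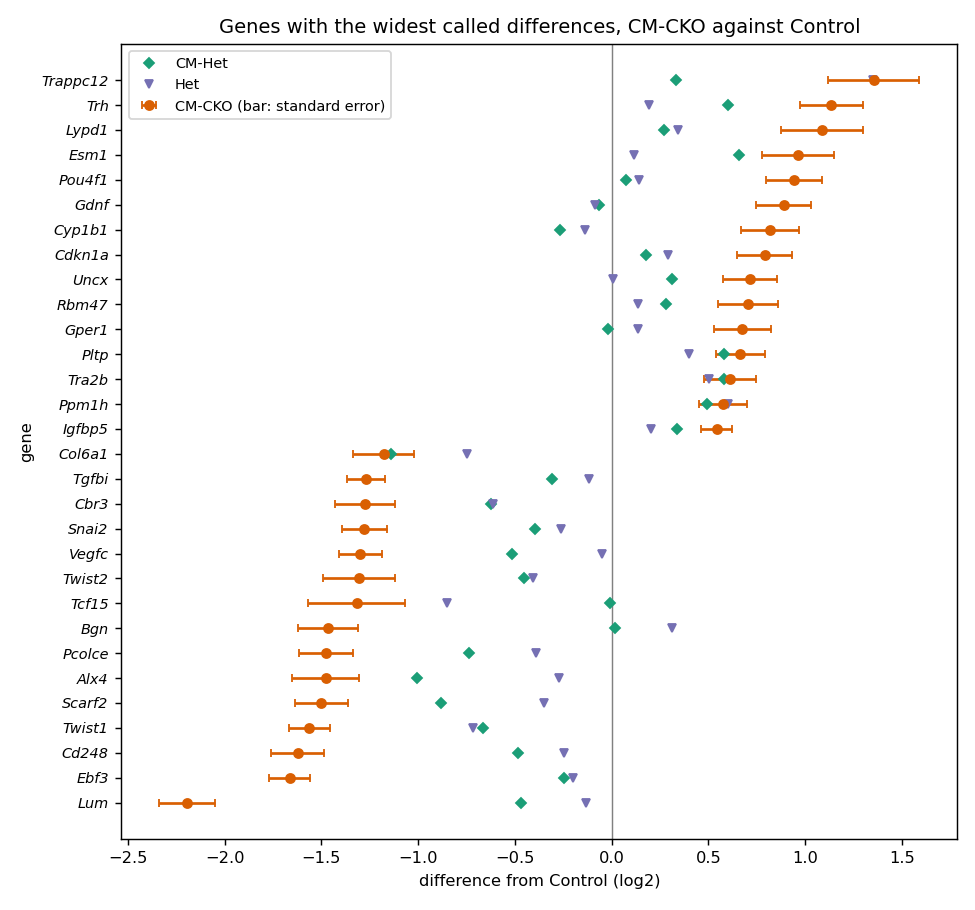
Differences from Control (log2, horizontal axis) of the 15 genes with the largest positive and the 15 with the largest negative called differences in CM-CKO (circles with standard errors), with CM-Het (diamonds) and Het (triangles) beside them. Lum has the widest difference in CM-CKO, -2.19, and for Bgn neither CM-Het nor Het lies below Control.

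All 80 genes kept their direction within beadchip 2 and with the CM-CKO arrays of beadchip 3. Fewer were called, 27 genes (4 higher, 23 lower) with the beadchip as a fixed block, 13 lower genes with the arrays of beadchip 2 alone and 24 with the CM-CKO arrays of beadchip 3 alone. Here and in both averages, only CM-CKO 1 and 2 stand for CM-CKO in the difference given by the block. Its differences from Control therefore equal those within beadchip 2, and only the errors differ. A call lost with the block can follow from fewer CM-CKO arrays as well as from the beadchip. Esm1 and Rbm47 differed by 1.03 and 0.47 with the block, against 0.96 and 0.70 over all arrays. Trh, Pou4f1 and Igfbp5 among the higher genes kept their call with the block, as did Lum, Ebf3, Cd248, Twist1, Scarf2, Alx4, Pcolce, Bgn, Twist2, Vegfc, Snai2, Cbr3, Tgfbi and Col6a1. Trappc12 (adjusted p = 0.0769), Tcf15 (0.113), Gdnf (0.118), Cyp1b1 (0.14), Cdkn1a (0.22), Esm1 (0.111), Lypd1 (0.252), Uncx (0.14), Pltp (0.105), Rbm47 (0.5), Gper1 (0.488), Tra2b (0.34) and Ppm1h (0.459) lost it. Of all 40 named calls 22 were lost. Without CM-CKO 4, 53 genes were called. Tcf15 lost its call without CM-CKO 1 (adjusted p = 0.0522). Esm1, Lypd1 and Uncx each lost theirs with any of 5 arrays left out (highest adjusted p 0.0623 without Control 4, 0.0769 without CM-CKO 4 and 0.0598 without Control 1), Pltp with any of 4 (0.0611 without CM-CKO 3). Rbm47, Tra2b and Ppm1h lost theirs with any of 10 arrays left out and Gper1 with any of 13 (highest adjusted p 0.184, 0.145, 0.167 and 0.101), so these 4 calls stand at the threshold. CM-CKO 3 and 4, but no Control array, lacked Xist signal, and 28 genes were called without them and Het 3. That omission also leaves CM-CKO 1 and 2 against Control, so it is not separate from the fit within beadchip 2.

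Among the gene lists, the head mesenchyme transcription factors fell most clearly. Of 20 measured members 18 were lower in CM-CKO (median log2 -0.32), 5 of them called over all genes and 7 lower adjusted over the list alone (camera adjusted p = 1.4e-13). The called members are Ebf3, Snai2, Alx4, Twist2 and Tcf15. Extracellular matrix components fell as well, with 29 of 37 lower (median log2 -0.25), 7 called lower, and 12 lower and 1 higher adjusted over the list alone (camera adjusted p = 1.74e-09). Lum, Pcolce, Bgn and Col6a1 lead that list. Endothelial genes fell with 21 of 24 lower (median log2 -0.29), 2 called, and 10 lower and 1 higher adjusted over the list alone (camera adjusted p = 4.78e-09). Its called members are Egfl7 (log2 -0.29, SE 0.06, adjusted p = 0.0416) and the tight junction gene Cldn5 (log2 -0.79, SE 0.18, adjusted p = 0.0462), and each lost its call with any of 11 arrays left out (highest adjusted p 0.146 without CM-CKO 3 and 0.145 without CM-CKO 4) and with the beadchip as a block (adjusted p = 0.14 and 0.187). Emcn (-0.60) and Esam (-0.38) passed only adjusted over the list alone (0.00317 and 0.0034). These 3 lists kept their call with an estimated correlation (adjusted p = 0.000178, 0.0436 and 0.0272) and with the beadchip as a block (medians -0.36, -0.18 and -0.25).

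Other mesodermal lists passed with the preset correlation only. Mesenchymal state genes had a median of -0.13 (camera adjusted p = 0.00499; adjusted p = 0.242 with an estimated correlation), with Pdgfrb (log2 -1.08), Pdgfra (log2 -0.69) and the intermediate filament gene Vim (log2 -0.56) called lower, and 4 lower and 1 higher adjusted over the list alone, the higher one being Cdh2 (0.44). The call of Pdgfra was lost without Control 3, CM-CKO 3 or CM-CKO 4 (highest adjusted p 0.0717), and with the beadchip as a block all 3 were lost (adjusted p = 0.0988, 0.253 and 0.171). Cell-matrix receptors had a median of -0.07 (camera adjusted p = 0.0161; adjusted p = 0.228 with an estimated correlation), with the integrin Itga9 called lower (log2 -0.80, adjusted p = 4.67e-05), the 1 member also lower adjusted over the list alone. That list lost its call without CM-CKO 2 and with the block (adjusted p = 0.0692). Twist1 and its partners had a median of -0.04 and a mean of -0.28, since Twist1 and Twist2 alone fell, also adjusted over the list alone (camera adjusted p = 0.0259; adjusted p = 0.336 with an estimated correlation), while Id4 (0.24) and Tcf3 (-0.20) did not pass. Without Control 3, Control 4 or CM-CKO 2, and with the block (adjusted p = 0.0692), that list lost its call. Since Twist1, the gene deleted by design, is a member, part of this call was set in advance and says little about the partners. The branchiomeric and pharyngeal mesoderm list did not shift (median log2 -0.02, 5 of 10 lower, camera adjusted p = 0.811). Its members of smallest p were Foxf1 (-0.39), Tcf21 (-0.29), Fgf10 (0.19) and Tbx1 (0.17), with 0 called, 0 adjusted over the list alone, and limma adjusted p from 0.366.

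Neural tube genes were slightly higher (median log2 0.15, 18 of 25 higher, camera adjusted p = 0.0259; adjusted p = 0.344 with an estimated correlation), and the list lost its call without Control 1, Control 3 or CM-CKO 2. It also lost it with every detected probe. Of the fits chosen after seeing the data, it lost it with the heart score as a covariate and with the deposited order of detection p in the filter. Pax8 (log2 0.52, SE 0.12, adjusted p = 0.047) was its 1 called member and lost that call with any of 12 arrays left out (highest adjusted p 0.156) and with the beadchip as a block (0.378). Adjusted over the list alone 3 members were higher, among them Fgf8 (0.36), and 2 lower, Zic1 (-1.34) and Nes (-0.51). Retinoic acid genes had a median of -0.29 (9 of 10 lower, camera adjusted p = 0.00485; adjusted p = 0.228 with an estimated correlation), with 0 called, and adjusted over the list alone Hoxb1 (-0.56) and Crabp1 (-0.48) lower and Cyp26a1 (0.42) higher. Without Control 1 this list lost its call. Yolk sac endoderm genes, a marker of attached tissue, were lower in 9 of 9 (median log2 -0.76, camera adjusted p = 0.000228; adjusted p = 0.344 with an estimated correlation), with 0 called and 0 adjusted over the list alone, among them Ttr (-1.81, SE 0.80) and Apom (-1.02, SE 0.46). That difference rests on Control 1, without which the list lost its call. Its mean log2 signal was 8.12 in Control 1 and 5.37 to 6.59 on the other 13 arrays.

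The remaining lists did not pass. Heart muscle genes had a median of -0.44 (camera adjusted p = 0.0836), with Nppa at -1.15 (SE 0.56), and their mean signal varied from 6.39 to 9.04 between arrays. Neural crest genes had a median of 0.02 and a mean of -0.03 (adjusted p = 0.472), and adjusted over the list alone Sox9 (-0.23) and Crabp1 (-0.48) were lower. Gut endoderm genes had a median of 0.13 (adjusted p = 0.083) with Trh called higher, FGF readouts of 0.14 (adjusted p = 0.0836) with Fgf8 higher adjusted over the list alone, surface ectoderm of 0.10 (0.242), epithelial state of 0.04 with a mean of -0.01 (0.852), erythroid cells of 0.15 (0.242) and myeloid cells of -0.04 (3 measured, 0.811). Tal1, which marks blood and vessel precursors, was called lower in the erythroid list (log2 -0.75, SE 0.13, adjusted p = 0.00845), against its direction. Among the pathways, medians were 0.00 for WNT (adjusted p = 0.289) with Sp5 called higher (log2 0.50, adjusted p = 0.00402), 0.05 for NOTCH (0.472) with Hey1 called higher (log2 0.45, adjusted p = 0.0178; lost without Control 2, Control 3, Control 4 or CM-CKO 4, at most 0.0846), 0.06 for hedgehog (0.494) and 0.06 with a mean of -0.05 and a downward test for BMP and TGF-beta (0.811), where Tgfbi was called lower. The p53 targets had a median of 0.01 (0.675), with Cdkn1a called and Trp53inp1 (0.34) also higher adjusted over the list alone. Cell division (median 0.00, adjusted p = 0.811), hypoxia and glycolysis (median -0.02, adjusted p = 0.852; Ndrg1 at -0.56 lower adjusted over the list alone) and immediate early genes (median -0.08, adjusted p = 0.179) did not pass. Adjusted over the list alone each single called member named here also passed. With the beadchip as a block Tal1 (adjusted p = 0.0565), Sp5 (0.113) and Hey1 (0.22) lost their calls.

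**Figure D3:**
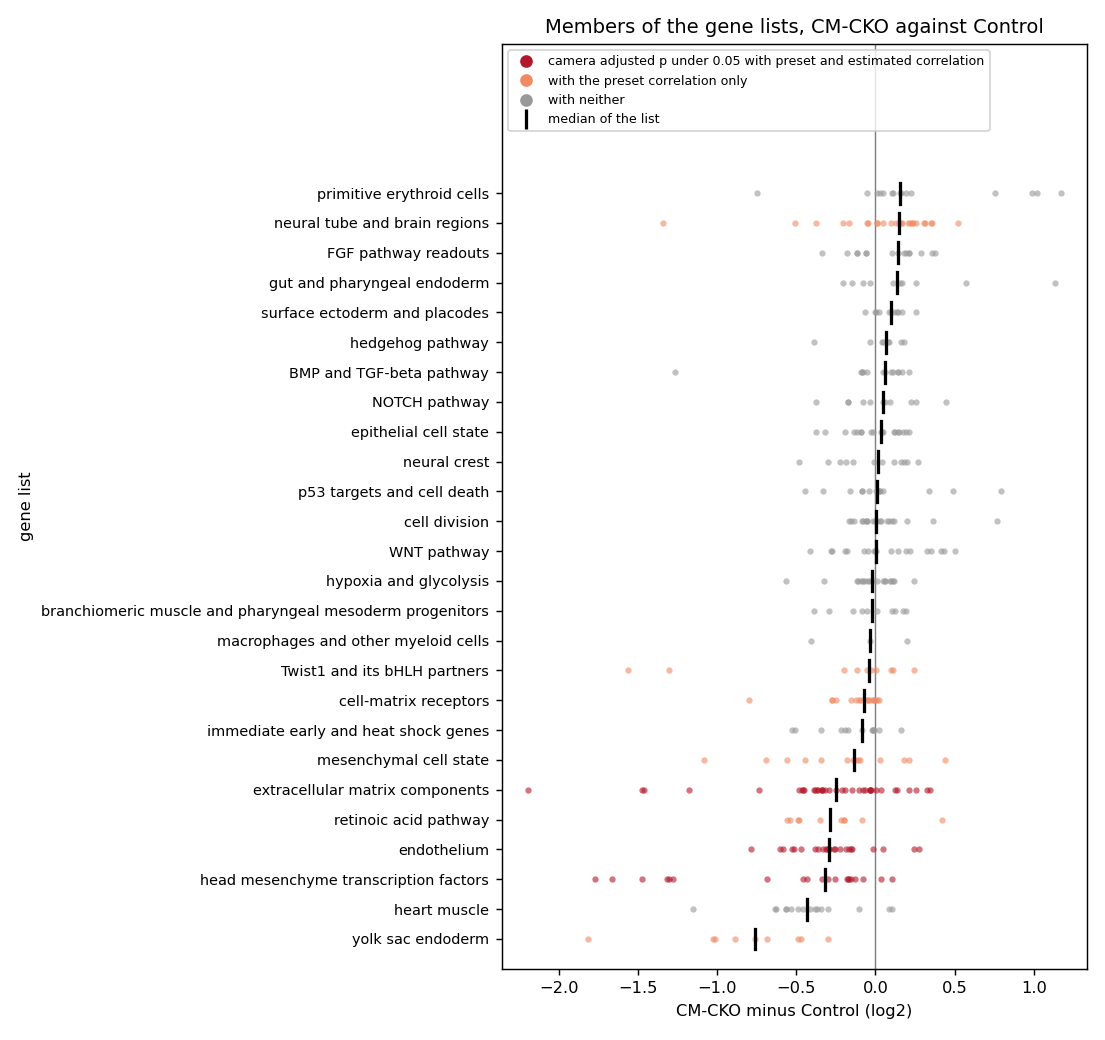
Differences of CM-CKO from Control (log2, horizontal axis) for every measured member of 26 gene lists (vertical axis), with black bars for the list medians and colours for the camera calls. The medians of head mesenchyme factors (-0.32), endothelium (-0.29) and matrix (-0.25) lie below 0 and pass with both correlations.

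CM-CKO against Het adds Mesp1-Cre, and with it the loss of the second copy in its lineage, so Cre itself is not held constant. Lum (log2 -2.06, SE 0.15, adjusted p = 2.07e-06), Bgn (-1.78), Ebf3 (-1.47), Cd248 (-1.38), Vegfc (-1.25) and Alx4 (-1.21) were lower, and Gdnf (0.98, SE 0.16, adjusted p = 0.0065), Cyp1b1 (0.96), Trh (0.94), Pou4f1 (0.80) and the endosomal ATPase Vps4b (0.68) higher. The mean of Vps4b was 5.25 in Het, 5.92 in CM-CKO and 5.69 in Control. Limma called 25 genes, 5 higher and 20 lower. Head mesenchyme factors (median log2 -0.15, 16 of 20 lower, 3 called, 6 lower adjusted over the list alone, camera adjusted p = 1.48e-07) and endothelium (median -0.23, 21 of 24 lower, 0 called, 10 lower adjusted over the list alone, camera adjusted p = 2.16e-08) fell and kept their call with an estimated correlation (adjusted p = 0.00261 and 0.0291). Matrix genes (median -0.07, 3 called and 6 lower adjusted over the list alone, camera adjusted p = 9.04e-05; adjusted p = 0.223 with an estimated correlation) and Twist1 with its partners (median -0.10, 1 called and 3 lower adjusted over the list alone, 0.00524; adjusted p = 0.247 with an estimated correlation) did not. Heart muscle (median 0.49, 0 called, 0 adjusted over the list alone, camera adjusted p = 0.0146; adjusted p = 0.722 with an estimated correlation) and FGF readouts (median 0.12, 0 called, 2 higher adjusted over the list alone, 0.00314; adjusted p = 0.223 with an estimated correlation) were higher by camera. Het lies on beadchip 1 and CM-CKO on 2 and 3, and with the beadchip as a random block, whose estimated correlation was negative (-0.0585) and so narrows the errors between beadchips, 40 genes were called. Without Het 1 or Het 2, 13 genes were called. Calls lost on leaving out 1 array were those of Alx4 (Het 1 or Het 2, adjusted p up to 0.0766), Cyp1b1 and Gdnf (Het 1, 0.122 and 0.0568), Trh (Het 1, Het 2, CM-CKO 3 or CM-CKO 4, up to 0.214), Pou4f1 (any of 9 arrays, up to 0.222) and Vps4b (any of 10, up to 0.314).

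CM-CKO against CM-Het holds Cre constant and changes the second allele. Lum (log2 -1.72, SE 0.15, adjusted p = 1.81e-05), Bgn (-1.48), Ebf3 (-1.42), Cd248 (-1.14), Tgfbi (-0.96) and Twist1 (-0.90) were lower. Cyp1b1 (1.09, SE 0.16, adjusted p = 0.00538), Gdnf (0.96), Pou4f1 (0.87), Vps4b (0.81) and the ventral neural tube factors Nkx6-2 (0.83) and Nkx6-1 (0.58) were higher. For Vps4b, Nkx6-2 and Nkx6-1 the Control means (5.69, 5.75 and 8.38) also lay above those of CM-Het (5.12, 5.11 and 8.15). Their CM-CKO means were 5.92, 5.94 and 8.73, so part of each difference is a low value in CM-Het. Limma called 24 genes, 8 higher and 16 lower. Head mesenchyme factors fell (median -0.24, 17 of 20 lower, 2 called, 5 lower adjusted over the list alone, camera adjusted p = 3.7e-07; adjusted p = 0.00275 with an estimated correlation). Matrix genes (median -0.03, 2 called, 6 lower adjusted over the list alone, 0.0239; adjusted p = 0.601 with an estimated correlation) and endothelium (median -0.13, 0 called, 1 lower adjusted over the list alone, 0.00807; adjusted p = 0.506 with an estimated correlation) passed with the preset correlation only, as did heart muscle upward (median 0.67, 0 called, 0 adjusted over the list alone, 0.0162; adjusted p = 0.682 with an estimated correlation). CM-Het lies on beadchip 1 and CM-CKO on 2 and 3, and 53 genes were called with the beadchip as a random block of the same negative correlation. The count fell to 11, 10 and 13 without CM-Het 1, 2 and 3 and to 13 without CM-CKO 1. Calls were lost for Gdnf and Vps4b (CM-Het 1 or 2, adjusted p up to 0.0752 and 0.0914), Pou4f1 (CM-Het 2, CM-Het 3, CM-CKO 1 or CM-CKO 3, up to 0.195), Nkx6-2 (any of 5 arrays, up to 0.143) and Nkx6-1 (any of 10, up to 0.221).

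CM-Het against Control, which adds Mesp1-Cre and with it the loss of 1 copy in its lineage, gave 47 calls, 21 higher and 26 lower. Among the lower ones were the collagen chain Col6a1 (log2 -1.14, SE 0.17, adjusted p = 0.0223), Alx4 (-1.01), Serpinf1 (-0.88) and Scarf2 (-0.88). The myosin Myo7a (-1.23), within 20 Mb of Mesp1, and Fhod3 (-0.74), an actin regulator of heart muscle, were lower too. Histone genes H2bc18 (1.07, SE 0.22, adjusted p = 0.0456), H2bc21 (0.78) and H3c7 (0.66), and Zfp568 (at least 1.48-fold, below background in Control), Scrn3 (0.81) and Gm7609 (0.74) were higher. Matrix genes (median -0.16, 2 called and 6 lower adjusted over the list alone, camera adjusted p = 0.00511), cell-matrix receptors (median -0.21, 0 called, 3 lower adjusted over the list alone, 0.014), head mesenchyme factors (median -0.15, 1 called, 1 lower adjusted over the list alone, 0.045) and heart muscle (median -1.14, 16 of 16 lower, 0 called, 0 adjusted over the list alone, 0.000256) were lower by camera, and all 4 lost that with an estimated correlation (adjusted p = 0.504, 0.321, 0.321 and 0.723). The heart muscle mean was 6.64 to 6.89 in CM-Het, near Control 2 and 4 (6.87 and 6.67) and below Control 1 and 3 (9.04 and 8.76). Each genotype lies on its own beadchip here, so beadchip and genotype cannot be told apart. None of the named calls outlasted every omission of 1 array. Without CM-Het 1, CM-Het 2 or Control 3 limma called 0 genes (1288, 1567 and 1741 at an unadjusted p under 0.05), and without Control 1, Het 2, CM-Het 3, CM-CKO 4, Control 4, Het 1, Het 3, Control 2 and CM-CKO 2 it called 1, 5, 6, 11, 14, 16, 16, 20 and 20. With the heart score as a covariate, chosen after seeing the data, 15 genes were called.

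In Het against Control limma called 0 genes, with 1418 at an unadjusted p under 0.05. Heart muscle (median -0.98, 16 of 16 lower, camera adjusted p = 0.000303), yolk sac endoderm (median -0.70, 9 of 9 lower, 0.0104), head mesenchyme factors (median -0.15, 17 of 20 lower, 0.0168) and retinoic acid genes (median -0.38, 8 of 10 lower, 0.0228) were lower by camera, with 0 members called in each, and 0, 0, 1 and 1 lower adjusted over the list alone. None kept this with an estimated correlation (adjusted p = 0.66, 0.66, 0.185 and 0.516). The heart muscle mean was 9.04 and 8.76 in Control 1 and 3 but 6.87 and 6.67 in Control 2 and 4, beside 6.53, 6.42 and 7.68 in Het 1, 2 and 3, and the yolk sac mean stood apart in Control 1 (8.12). Left out singly, CM-Het 1 gave 5 calls, Control 2 and CM-CKO 1 gave 2 each and the other 11 arrays 0. With the beadchip as a random block 83 genes were called, but its correlation of -0.0585 narrows the errors between beadchips (for Twist1 from an SE of 0.113 to 0.102) and so does not correct for them. Beadchip and genotype cannot be told apart here either. CM-Het against Het, both on beadchip 1 with 1 intact copy in the Cre lineage, gave 0 calls by limma and 451 genes at an unadjusted p under 0.05. Branchiomeric progenitor genes (median 0.16, 9 of 10 higher, camera adjusted p = 0.00326) and FGF readouts (median 0.11, 13 of 15 higher, 0.00505) were higher and neural crest (median -0.29, 11 of 12 lower, 0.000408) and endothelium (median -0.14, 17 of 24 lower, 0.0285) lower in CM-Het, with 2, 0, 0 and 0 members adjusted over the list alone. None of these kept its call with an estimated correlation (adjusted p = 0.253, 0.253, 0.253 and 0.386).

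Of the 59 genes lower in CM-CKO than in Control, 58 were below Control in CM-Het, 57 in Het, and 56 lay between Control and CM-CKO in both. Their median differences from Control were -0.83 in CM-CKO, -0.35 in CM-Het and -0.22 in Het. Of the 21 higher genes 18 were above Control in CM-Het, 19 in Het and 17 between in both (medians 0.67, 0.27 and 0.14). Shared Control arrays raise such shares. Lower genes were also lower in 98.3% (CM-Het) and 96.6% (Het), against 55.4% and 55.3% on average in simulations of unchanged groups (highest 78.7% and 72%) and 67.8% to 100% and 67.8% to 94.4% with the Control arrays divided between the comparisons. Higher genes gave 85.7% and 90.5%, against 57.8% and 57.0% (highest 93.3% and 81.3%), so for CM-Het the share of higher genes lies within the simulated range. CM-CKO against Het shared 16 lower and 4 higher calls with CM-CKO against Control, among them Lum, Bgn and Ebf3, where independent lists would share 0.104 and 0.00922. CM-CKO against CM-Het shared 10 and 3 (independent lists 0.0829 and 0.0147), and CM-Het against Control 9 and 0 (0.135 and 0.0387). Unchanged simulated groups shared 0, and with the common arrays divided between the comparisons 11 to 15, 6 to 9 and 0 to 8 calls were shared.

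**Figure D4:**
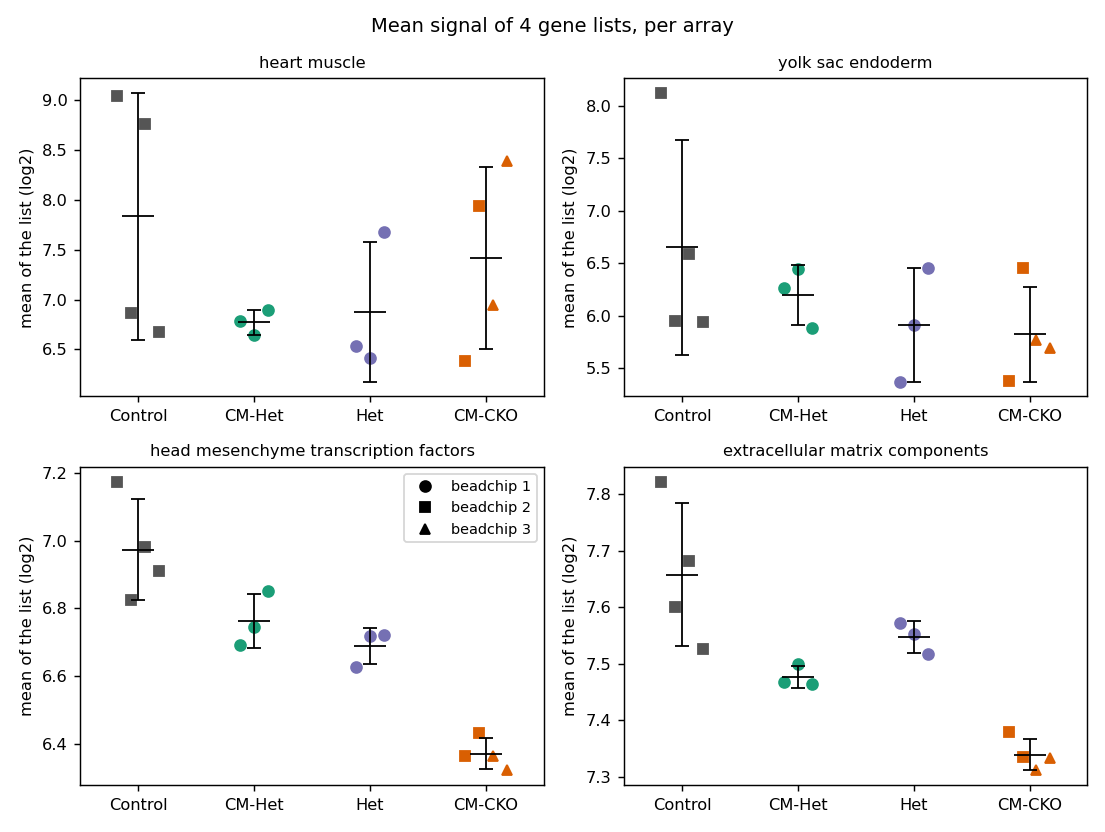
Mean log2 signal of the members of 4 gene lists on each array, by genotype, with symbols for the beadchip and black bars for the mean and SD. Heart muscle spreads from 6.39 to 8.39 within CM-CKO, whereas all 4 CM-CKO arrays lie below all others for head mesenchyme factors and for matrix components.

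Averaged over the second allele, Cre lowered Lum (log2 -1.27, SE 0.11, adjusted p = 2.02e-05), Alx4 (-1.11), Scarf2 (-1.02), Cd248 (-0.93), Pcolce (-0.91), Vegfc (-0.88) and Twist1 (-0.75), and raised Trh (0.77, SE 0.12, adjusted p = 0.00581), Esm1 (0.75), Igfbp5 (0.34) and Socs2 (0.33). It called 30 genes, 4 higher and 26 lower, and 21 with the beadchip as a fixed block. Beside the wild-type and the deleted allele Cre gave -0.47 and -2.06 for Lum, -0.48 and -1.38 for Cd248 and -0.51 and -1.25 for Vegfc, all 3 called in the interaction. Esm1 and Igfbp5 lost their calls with the beadchip block (adjusted p = 0.0712 and 0.103). Esm1 also lost its call with any of 9 arrays left out (up to 0.101 without Het 1), and Igfbp5 without CM-Het 1, CM-Het 3, Het 1 or Het 3 (up to 0.0847). Head mesenchyme factors (median -0.17, 17 of 20 lower, 3 called, 5 lower adjusted over the list alone, camera adjusted p = 8.31e-09) and endothelium (median -0.23, 19 of 24 lower, 0 called, 11 lower adjusted over the list alone, 7.33e-09) fell and kept this with an estimated correlation (adjusted p = 0.00138 and 0.0243). Matrix genes (median -0.14, 28 of 37 lower, 4 called, 10 lower and 1 higher adjusted over the list alone, 8.31e-09) just lost it (adjusted p = 0.0581 with an estimated correlation). Passing with the preset correlation only were Twist1 with its partners (-0.10), cell-matrix receptors (-0.10) and neural crest (-0.18) downward, and gut endoderm (0.08) and FGF readouts (0.13) upward (camera adjusted p = 0.006, 0.00598, 0.00184, 0.00598 and 0.00106; adjusted p = 0.216, 0.107, 0.264, 0.101 and 0.101 with an estimated correlation), with 2 lower, 1 lower, 0, 1 higher and 2 higher adjusted over the list alone.

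Averaged over Cre, the deleted allele lowered Tcf15 (log2 -1.08, SE 0.19, adjusted p = 0.0356), Lum (-0.93), Twist1 (-0.81, SE 0.08, adjusted p = 8.92e-05), Ebf3 (-0.81), Cd248 (-0.70), Snai2 (-0.57), Tgfbi (-0.54), Col26a1 (-0.41) and Itga9 (-0.39), and its 1 higher call was the unsettled Trappc12. These were all 10 calls. For Lum, Ebf3, Tgfbi and Cd248 the average covers unequal parts, -0.13, -0.20, -0.11 and -0.25 without Cre and -1.72, -1.42, -0.96 and -1.14 with it, and all 4 were also called in the interaction (adjusted p = 0.00492, 0.00466, 0.0175 and 0.0495). With the beadchip as a fixed block 7 genes were called, and Snai2, Col26a1, Itga9 and Tcf15 lost theirs (adjusted p = 0.0574, 0.0574, 0.104 and 0.109), and Tcf15 with any of 9 arrays left out (up to 0.156), Itga9 with any of 6 (up to 0.126) and Col26a1 without CM-Het 2 or 3 (up to 0.0794). Head mesenchyme factors fell (median -0.18, 16 of 20 lower, 3 called, 8 lower adjusted over the list alone, camera adjusted p = 1.55e-10; adjusted p = 0.000545 with an estimated correlation). With the preset correlation only, the branchiomeric (-0.08), matrix (-0.05), mesenchymal state (-0.08), endothelium (-0.06), yolk sac (-0.54) and retinoic acid (-0.18) lists were lower and neural tube (0.07) and WNT genes (0.07) higher (camera adjusted p = 0.0162, 6.99e-05, 0.0057, 0.00764, 0.000264, 0.00242, 0.0208 and 0.0153; adjusted p = 0.243, 0.212, 0.243, 0.243, 0.33, 0.212, 0.33 and 0.212 with an estimated correlation), with 0, 8, 3, 0, 0, 0, 0 and 1 members adjusted over the list alone.

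Whether the Cre effect differed with the second allele was read from the interaction, which also takes up any shift between beadchips 1 and 2. It called 114 genes, 31 higher and 83 lower. Bgn (log2 -1.79, SE 0.24, adjusted p = 0.00466) and Lum (-1.59, SE 0.22, adjusted p = 0.00492) had lower values, with Cre differences of -1.78 and -2.06 beside the deleted allele and of 0.02 and -0.47 beside the wild-type allele. Cyp1b1 (1.22), Vps4b (1.25), Ndufb4 (1.11) and Cox7b (1.05) were higher. The histone genes H4c12 (-1.81) and H2bc18 (-1.61) and the mitochondrial gene ND5 (-1.75) were lower, with CM-Het and Het both above Control and CM-CKO. Zfp568, above background on 0 of 4 Control arrays, and Mybphl and Cpa1, on 0 arrays of CM-Het and Het, were called as well. For these 3 the size is not measured. Heart muscle was the only list past the threshold (median 1.63, 16 of 16 higher, 0 called, 0 adjusted over the list alone, camera adjusted p = 5.49e-05; adjusted p = 0.851 with an estimated correlation). Counts fell to 22, 64 and 36 without CM-Het 1, 2 and 3, to 45, 27 and 56 without Het 1, 2 and 3, to 74 and 53 without Control 1 and 4 and to 45 and 61 without CM-CKO 1 and 2. Of the 12 genes, Bgn, Lum, Vps4b and Zfp568 kept their call with each array left out, and the others lost it with 2 to 13 of the 14 arrays (adjusted p up to 0.128).

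DNA from the strain of the targeted embryonic stem cells can travel with an engineered allele, so genes near both loci were compared with the rest. Within 10 Mb of Twist1 on chromosome 12, 1 of 45 genes was called for the deleted allele (Trappc12, of unsettled direction; Fisher exact p = 0.035, but 0.06 within 20 Mb with the same gene and 1 within 5 Mb with 0 of 25), and 26.7% had an unadjusted p under 0.05 against 7.16% elsewhere. For the deleted allele 2 probes of Trappc12 passed in opposite directions, 1.19 and -1.14 (limma adjusted p = 0.0103 for each over all detected probes). A further probe read 0.08. In Control, CM-Het, Het and CM-CKO the first stood at 4.88, 5.21, 6.23 and 6.23, and the second at 6.03, 5.86, 4.79 and 4.81. Both thus followed the deleted allele with and without Cre. Twistnb, next to Twist1, differed by -1.95 (SE 0.50), Mboat2 by -0.85 and Prkar2b by -0.56, and none of these 3 passed (limma adjusted p = 0.262, 0.156 and 0.166). Within 10 Mb of Mesp1 on chromosome 7, limma called 0 of 69 genes for Cre (Fisher exact p = 1), with 14.5% at an unadjusted p under 0.05 against 7.20% elsewhere. Within 20 Mb 1 of 133 was called, Mogat2, an acylglycerol transferase (log2 -0.61), for which both probes fell (-0.61 and -0.78, adjusted p = 0.00777 and 0.0322 over all detected probes). Also called for Cre on chromosome 7, outside that window, were Mrpl48 (-0.43), Coa4 (-0.52), Ppfibp2 (-0.62) and Ebf3 (-0.86). Other probes of Mrpl48 read -0.38 and -0.0018. These named neighbours, and the further genes of chromosome 7, were chosen after their values were seen.

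**Figure D5:**
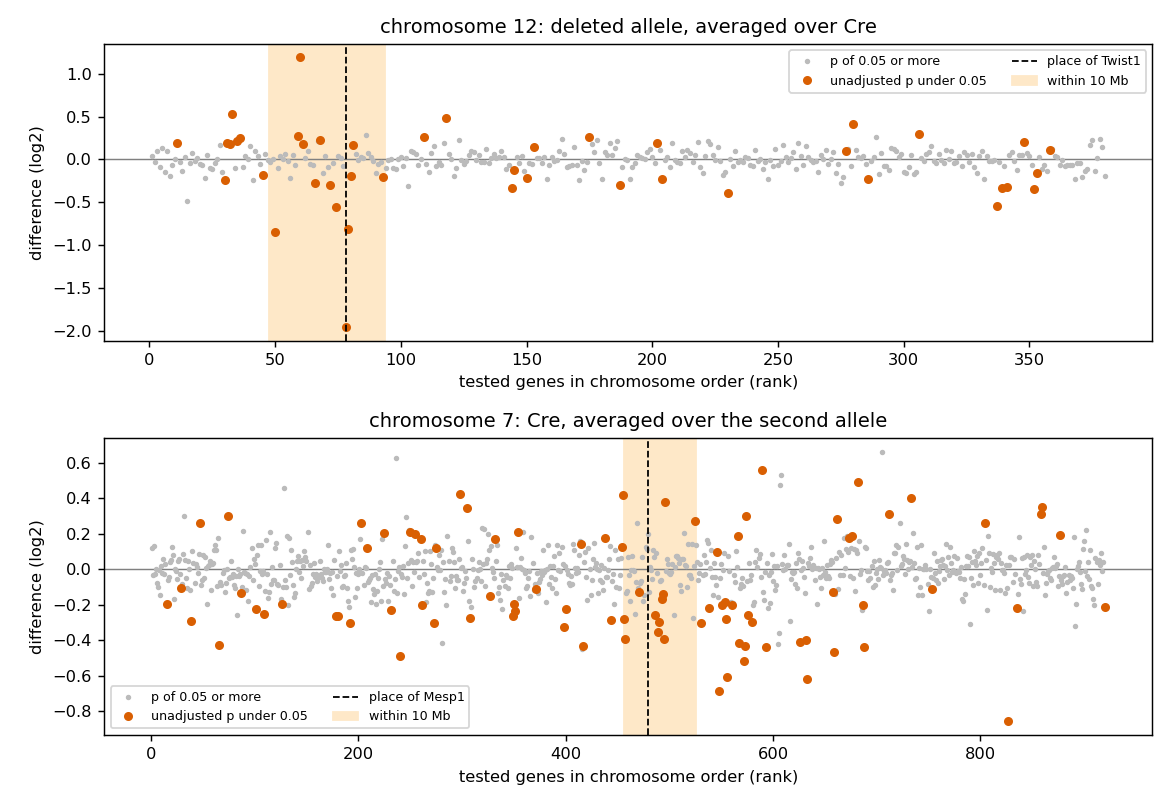
Differences (log2, vertical axis) of all tested genes in chromosome order, for the deleted allele on chromosome 12 (top) and for Cre on chromosome 7 (bottom), with orange points at an unadjusted p under 0.05 and shading within 10 Mb of Twist1 and Mesp1. Orange points make up 26.7% of the 45 genes in the upper and 14.5% of the 69 genes in the lower shaded part.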

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

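Chosen after the results were seen were the test of a beadchip difference for the interaction, all 4 tests at the engineered loci, the test of a lower share of mesodermal cells, the values for 15 listed genes and the regroupings with heart signal in the fit. The heart covariate of both tests on heart tissue was also chosen after seeing the data, though their bounds were set before their results. The bound of the test on mesodermal cells was also moved, from 1 to 2 standard errors, after its value was known, and the bound of the tests on loss of function at the loci was changed to a comparison with genes chosen at the same p.

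In groups of 4 arrays, 4 values lay far from the other 3. They were Gdnf in Control 2 (log2 5.16, others 5.57 to 5.59), Igfbp5 in Control 2 (11.9, others 12.2 to 12.3), the mean of the BMP and TGF-beta genes in Control 2 (7.65, others 7.79 to 7.81) and the mean of the neural tube genes in CM-CKO 1 (7.93, others 7.83 to 7.85). Chance gives about 1 in 20 groups, or 5.9 of the 118 tested, so 4 is no excess. Among 3109 detected probes without a single gene symbol, which stand outside the gene tests, 7 were called by limma in CM-CKO against Control and 143 in the interaction.

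The effect of Cre differed with the second Twist1 allele for 114 genes by the interaction term of limma. The largest named differences were as follows, where the values of Mybphl, Cpa1 and Zfp568 include a group with no array above background and are not measured sizes. They were 1.33 for Mybphl, 1.25 for Vps4b, 1.22 for Cyp1b1, 1.11 for Cpa1, 1.11 for Ndufb4, 1.05 for Cox7b, -1.81 for H4c12, -1.79 for Bgn, -1.75 for ND5, -1.61 for H2bc18, -1.59 for Lum and -1.52 for Zfp568. Of the 106 genes not also called in CM-CKO against Control, 93.4% had CM-Het and Het on the same side of Control and both further from it than CM-CKO, against 34.3% among genes not called. The choice of these genes, by a called interaction without a called difference of CM-CKO from Control, itself favours this order. The genes not called were not chosen in that way, so their share is no matched comparison. A beadchip difference could give this order, because CM-Het and Het fill beadchip 1, and within CM-CKO limma called 0 genes between beadchips 2 and 3 (654 at an unadjusted p under 0.05), so beadchip and genotype cannot be told apart here. Heart tissue carried along stays open too, since 64.0% of the count, 73 genes, remained with the heart muscle mean as a covariate. A biological difference between 1 and 0 intact copies under Cre also stays open.

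Genes near the engineered loci shifted more often than genes in other windows of the same width. For the deleted allele 26.7% of genes in the 20 Mb around Twist1 had an unadjusted p under 0.05, and 0 of 436 other windows were as high. For Cre it was 18.0% in the 40 Mb around Mesp1, with 0 of 358 other windows as high. In the 20 Mb around Mesp1 it was 14.5%, with 10 of 436 as high. The ranks are the top 0.229%, 0.279% and 2.52% of windows. Windows overlap, so fewer separate stretches stand behind these ranks, and 0.229% and 0.279% are the smallest values possible. Flanking DNA that travels with either allele could give both excesses. Loss of Twist1 function would move these genes with the other allele as well, but its median effect on them was 15% (SE 12.1) of the own effect for 12 genes near Twist1 and -26.2% (SE 10.8) for 24 genes near Mesp1, against 13.3% and 19.4% for genes elsewhere chosen at the same p. These standard errors treat genes as independent, though all were measured on the same 14 arrays, and the errors of both averages are linked through those arrays. The ratios therefore do not decide on loss of function at either locus. For the other allele, 2.22% of genes around Twist1 and 7.52% around Mesp1 had an unadjusted p under 0.05. The medians of other windows were 7.32% and 7.19%, so the other allele gave no excess there. An effect of the engineered allele on its neighbours in cis was not tested.

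Mesenchyme and matrix genes were lower in CM-CKO than in Control. For a beadchip difference, the effect within beadchip 2 was set against that over all arrays. The median ratio was 0.970, with the same sign for all 80 called genes, and 0.939 for the 15 lower genes of the head mesenchyme, mesenchymal state and matrix lists. These genes were called on the same arrays, and a call favours genes alike on both beadchips. The ratio was therefore partly fixed in advance and does not decide for all 80 genes. Within beadchip 2 alone 13 lower genes were called, among them Lum, Ebf3, Bgn, Pcolce and Snai2. A difference between beadchips cannot give those calls. With the heart muscle mean as a covariate 87.5% of all called genes (70 of 80), and 14 of the 15 lower genes of these lists, stayed called. Heart signal varied within both genotypes, so a call already favours genes that do not follow it. That share was partly fixed in advance and does not decide on heart tissue carried along. The heart mean was 6.39 and 6.94 in CM-CKO 1 and 3, and 7.93 and 8.39 in CM-CKO 2 and 4. All 4 lay below every Control array in the means of the head mesenchyme and matrix lists, so these means did not follow the heart mean. A lower share of all mesodermal cells stays open, since the branchiomeric list lay 0.30 (SE 0.21) above the head mesenchyme list, beyond 1 standard error, the first bound, but within 2. That standard error was drawn over list members as if independent and holds no spread between arrays, so neither bound decides. Loss of expression within mesenchyme cells and loss of those cells cannot be told apart here.

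Arrays were also regrouped in every possible way within each comparison, or 100 ways for the averages and the interaction, to ask whether chance could give as many calls. In CM-CKO against Control 2 of 35 groupings, the real one included, gave at least its 80 genes, so chance cannot be excluded by this count. The highest other, 91, sets Control 2, Control 4, CM-CKO 1 and CM-CKO 3 against the rest, which is also low against high heart signal. With heart signal in the fit the real grouping gave 79 and the highest other 3. That covariate takes up the rival split by construction, so the fall from 91 is no separate evidence against chance. For the lists 5 of 35 groupings gave at least 9 (highest other 10, median of the others 3.5), so chance cannot be excluded there either. No other grouping gave as many genes in CM-CKO against Het (1 of 35, real 25, highest other 1). The same held for CM-CKO against CM-Het (1 of 35, 24 and 1) and CM-Het against Control (1 of 35, 47 and 6). It also held for the Cre average (1 of 100, 30 and 4) and the interaction (1 of 100, 114 and 54). A share of 1 of 35 is the smallest possible here, and the tests were not adjusted for their number. The counts therefore make chance less likely in each comparison taken singly but do not exclude it. Regroupings for the averages and the interaction mixed arrays of all genotypes, so they do not test those contrasts alone. CM-Het against Control also fell to 0 calls without CM-Het 1, CM-Het 2 or Control 3. For the deleted allele 2 of 100 groupings gave at least 10 genes, with 31 in the highest other, which passes the 5% bound though a larger count arose by chance. Het against Control and CM-Het against Het gave 0 genes, which all 35 and all 10 groupings reach by construction (highest others 50 and 0), so the count says nothing about chance there.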

How the results depend on the processing

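The heart covariate, the omission of the 3 arrays without Xist signal and the deposited order of the detection p were chosen after seeing the data. The random beadchip block had an estimated correlation of -0.0585, which narrows the errors between beadchips, so its higher counts are no correction for the beadchip. Counts of called genes, as main value and then alternatives, were as follows, and the cause was not tested except where fewer arrays or genes enter. CM-CKO against Control gave 80, then 123 at an adjusted p under 0.1, 53 with only the groups compared, 27 with the beadchip as a fixed block, 13 within beadchip 2, 24 with CM-CKO of beadchip 3, 28 without the arrays lacking Xist, 37 with the deposited order, and 53 to 78 with 1 array left out. CM-CKO against Het gave 25, then 42 at 0.1, 42 with array weights, 40 with a random beadchip block, 13 without the arrays lacking Xist, 16 with the deposited order, and 13 to 26. CM-CKO against CM-Het gave 24, then 55 at 0.1, 54 with weights, 53 with the random block, 14 with the replicate block, 5 without the arrays lacking Xist, 11 with the deposited order, and 10 to 30. CM-Het against Control gave 47, then 209 at 0.1, 110 with weights, 277 with the random block, 78 over every detected probe, 20 without a detection filter, 8 with only the groups compared, 23 without the variance trend, 11 with the replicate block, 15 with the heart covariate, 8 without the arrays lacking Xist, and 0 to 59. Het against Control gave 0, then 12 at 0.1, 3 with weights, 83 with the random block, 4 over every detected probe, 1 with median scaling, 1 with only the groups compared, and 0 to 5. CM-Het against Het gave 0 throughout by limma (312 to 920 genes at an unadjusted p under 0.05). The Cre average gave 30, then 51 at 0.1, 54 with weights, 16 with the deposited order, and 23 to 39. The deleted allele average gave 10, then 16 at 0.1, 16 with weights, 20 with the heart covariate, 4 without the arrays lacking Xist, 4 with the deposited order, and 7 to 14. The interaction gave 114, then 714 with the random block, 73 with the heart covariate, 20 with the replicate block, 28 without the arrays lacking Xist, and 22 to 96. Lists called in CM-CKO against Control were 9, then 3 with an estimated correlation, 4 with the deposited order, and 7 to 12. Calls near the loci were 1, then 2 within 20 Mb and 0 within 5 Mb. Twist1 in CM-CKO against Control stayed called at -1.26 to -1.63. The 117 named genes of that comparison, list members included, gave 3699 values over 32 settings, of which 17 turned direction. Only 40 of these genes were called, so only their values could lose a call, and 255 did. With the deposited order another probe stood for the gene, and turned were Pou4f1 (-0.0601; -0.0121 against Het; -0.00575 against CM-Het), Egfl7 (0.12), Aif1 (-0.0494), H2bc21 in CM-Het against Control (-0.18) and Col26a1 for the deleted allele (0.0357). With the fixed beadchip block, within beadchip 2 and without the arrays lacking Xist, Rab25 (-0.0143), Fgf15 (-0.0645) and Jun (0.0737) turned, none called before. Each of these fits compares CM-CKO 1 and 2 with Control and so gives the same differences. With CM-CKO of beadchip 3, Aif1 (-0.0372) and Csf1r (0.00347) turned. With 1 array left out, Slc4a1 ranged from -0.0422 to 1.11, Csf1r from -0.12 to 0.12 and Twist1 in CM-Het against Het from -0.0215 to 0.11, none called before. Replicate numbers do not pair the samples. Deviations of 19 pairs with the same number correlated at -0.237 to 0.251, 6 of 14 arrays fitted best with their own number, and a replicate block gave 71 calls in CM-CKO against Control. Signal near background limits dim genes to bounds on their fold.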

Other observations

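Xist as the mark of arrays without it, and the histone genes as a group, were chosen after the values were seen, and the set of histone names was narrowed after a first look. The histone genes were not tested as a group. Over 47 such genes, whose transcripts mostly lack a poly(A) tail, the median difference from Control was 0.37 in CM-Het (39 higher, 3 called) and 0.39 in Het (41 higher, 0 called by limma, 25 at an unadjusted p under 0.05), but 0.07 in CM-CKO. Against CM-Het and Het the median of CM-CKO was -0.29 and -0.31. Between CM-Het and Het it was -0.03. Without background correction the medians against Control were 0.22, 0.24 and 0.04, and with median scaling 0.34, 0.39 and 0.05.

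Tissue marker means varied between arrays of the same genotype. The heart muscle mean was 9.04 in Control 1, 8.76 in Control 3, 8.39 in CM-CKO 4, 7.93 in CM-CKO 2 and 7.68 in Het 3, and 6.39 to 6.94 on the other 9 arrays. Primitive erythroid genes, which mark yolk sac blood, had a mean of 7.46 in CM-CKO 1 and 5.51 to 6.35 elsewhere. Xist, expressed from the inactive X chromosome, was at 4.18 to 4.60 over its 4 probes on Het 3, CM-CKO 3 and CM-CKO 4 and at 7.87 to 10.5 on the other 11 arrays. The Y-linked gene Eif2s3y was at 4.24 on CM-Het 2, 4.28 on Het 1 and 4.31 on Control 3 and at 6.71 to 9.28 elsewhere, so 8 arrays show both. The sex-linked list had a median of 0.72 in CM-CKO against Control over 4 measured genes (camera adjusted p = 0.441), with 0 called and 0 adjusted over the list alone.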
